A study of Mus musculus with 2 samples.

How the data were processed

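Liver of B6NCrl mouse embryos at embryonic day 13.5, pooled from both sexes, was profiled by ChIP-seq for H3K36me3 in 2 biological replicates, each combining 2 technical replicates per the labels. Replicate numbers were taken from the labels, and both replicates belong to the same group. Each replicate has its own peak list, and there is a list called on both replicates together and a list of replicated peaks, which the file descriptions deposited with the samples say was derived from the replicate lists and the joint list. All lists are in narrowPeak form on mm10, per the deposited file descriptions. The aligner, the peak caller, its control and its settings are not given in the sources used here. Beyond the alignment of the sample, the file descriptions name 2 source files for the list of replicate 1 and 1 for that of replicate 2, without their roles. Whether the replicates were called against different controls is therefore unknown, which bears on every difference and overlap between them.

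Each deposited peak carries a signal value, the authors' own enrichment measure, which was used only to rank or describe peaks within a list. The deposited lists also give −log10 of a p-value and −log10 of a q-value per peak, and these served only as stricter filters. The lowest −log10 p-value was 2.01 in the list of replicate 1 and 2.00 in that of replicate 2. The files hold no read counts, so the depth is unknown and no precision from counting reads could be given. The replicates are described by the labels as biological, and with n = 2 their SD is a rough measure of spread.

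Peaks were placed on GENCODE mouse release 21, an annotation of GRCm38, which is the same assembly as mm10. Genes on the 19 autosomes, X and Y were used, 55413 in all, of which 21938 are protein-coding and 21221 of these are at least 1 kb long. Coordinates are counted from 1. RefSeq annotation release 108.20200622 of the same assembly was used for gene synonyms, for RefSeq models at peaks outside GENCODE genes, and for the sequence. Peaks on scaffolds were left out of gene comparisons. No records within a list overlapped, so merging them changed nothing.

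The covered share of a gene is the percent of its annotated body, introns included, that lies under peaks of a list. A gene was called marked with at least 20% covered in both replicates, low with under 5% in both and partly covered otherwise. Covered shares depend on peak calling and on mappability, and a gene inside or next to another marked gene takes over part of its coverage. The share of each gene's body inside other protein-coding genes was computed for this reason. Gene body enrichment is the covered share of protein-coding genes over that of sequence at least 5 kb from any gene. The difference between the 3' and 5' sides of the gene midpoint was taken in marked genes of at least 5 kb, with a profile of 10 bins and windows of 1 kb up to 5 kb on each side. Internal exons and introns came from the transcript with the greatest exon length of genes with at least 3 exons, and intron bases that are exonic in another transcript were left out.

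Gene lists, 25 in number with 2376 matched members, were fixed before the data were examined, 19 of them by name and 6 by patterns over symbols. The lists cover erythroid, hepatoblast, adult hepatocyte, coagulation and complement, cholangiocyte, stem and progenitor, megakaryocyte, myeloid, lymphoid, endothelial, mesenchymal, neuronal and muscle genes, developmental transcription factors, cell cycle, haem biosynthesis, general machinery, H3K36 methylation machinery and imprinted genes, and the ribosomal protein, Zfp, olfactory, vomeronasal, histone and keratin families. Some genes belong to several lists, such as Alas2, Fech and Cpox to the erythroid and haem lists. The median covered share of each list was ranked among 10000 random lists in which each member was replaced by one of the 200 protein-coding genes nearest in length, and a list was called above or below in the top or bottom 2.5%. That limit was set after the files had been opened and before any list was ranked. Replicate overlap was compared with 100 circular shifts of replicate 2 along each chromosome without gaps. Intervals of shares are exact binomial intervals at 95% and cover counting error only. No p-value between groups of samples was computed, since there is 1 group. The p-value printed for X and autosomal list members is over genes, which are not independent replicates.

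The named genes follow a rule set before the data were examined. They are the 20 protein-coding genes of at least 5 kb with the highest mean covered share, the 10 with the greatest covered length in the replicated list, the 10 longest with no covered base, the highest and lowest members of each list and every member of a list of 10 or fewer, 5 noncoding genes, the 10 with the largest replicate difference, the 10 intergenic peaks of highest signal and the 5 largest and 5 smallest 3' minus 5' differences. Further list members, Vps13d's position along the gene, Eif4a1 and Spta1 were singled out after their values were seen.

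The scripts were tested on simulated lists over the same 21221 genes, with peaks over the 3' part of 2000 genes and 4200 random peaks. The 2000 genes were drawn from those of at least 5 kb with no other annotated gene within 5 kb. Coverage that a gene takes over from an overlapping or adjacent gene was therefore not tested. All of the 2000 genes (100%) and 0 others were called marked, the 3' minus 5' difference was 63.9 points where 64 were built in, and the base overlap was 63.1% where 63.0% was built in. Of 100 lists without signal 0 were called by their median and 4 by the number of marked members, and 20 of 20 lists with 15 of 20 covered members were called. Fewer genes were covered than the 6045 marked in the data, so these counts do not give the rate of false calls there. Alternatives included stricter peak filters, other thresholds for marked genes, the series lists in place of the replicate lists, leaving out each replicate and other overlap rules. The scripts ran on Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.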

Results

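H3K36me3 was profiled by ChIP-seq in the liver of mouse embryos at embryonic day 13.5. H3K36me3 is a trimethyl mark on histone H3 that is laid down behind elongating RNA polymerase II, and the liver at this stage makes red blood cells as well as hepatic tissue. The samples formed 1 group of 2 biological replicates, each from B6NCrl embryos of both sexes pooled and each made of 2 technical replicates. Replicate 1 had 162299 peaks covering 103 Mb, or 3.9% of the genome without gaps, and replicate 2 had 156214 peaks covering 100.4 Mb, or 3.79%. A list called on both replicates together held 161253 peaks over 127 Mb, and a list of replicated peaks held 110088 peaks over 113 Mb. The files give no read counts, so the depth of each sample is unknown. With a single group, the comparisons are between the replicates and between genes and regions within each replicate. Values are the mean ± SD of the replicates, n = 2, unless stated.

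The 20 protein-coding genes of at least 5 kb with the greatest share of their body under H3K36me3 peaks included genes of DNA replication, mitosis and splicing. Top2a, the DNA topoisomerase of dividing cells, was covered over 96.5% ± 0.113 of its body (SD, n = 2), which lies on chromosome 11 from 98992943 to 99024189 in mm10. Mcm5 and Mcm2, subunits of the replicative helicase, reached 95.9% ± 0.626 and 92.0% ± 0.148, and the replication licensing factor Cdc6 reached 92.0% ± 2.55. The splicing factors Sf3a1, Sf3b3 and Prpf8 stood at 93.9% ± 0.0223, 92.4% ± 0.540 and 91.7% ± 0.147. Slc2a1, a glucose transporter, was at 95.7% ± 0.809, the mitotic genes Dlgap5, Ccnf and Ncapd2 were at 93.5% ± 0.353, 93.0% ± 0.464 and 92.5% ± 0.388, and the nuclear import receptor Kpnb1 was at 93.2% ± 0.241. Elmo3, Slc20a1, Tut7, Cars and Phykpl also ranked among the 20 highest, between 91.5% and 94.4%. Ankrd61, 4933428G20Rik and Gigyf1 completed the 20, but 100% of each lies inside another annotated protein-coding gene, whose coverage it shares.

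Of 21221 protein-coding genes of at least 1 kb, 6045 (28.5%) were marked, meaning that peaks covered at least 20% of the body in both replicates. A further 12343 had under 5% covered in both, 2833 lay between, and 9534 had no covered base in any of the lists. In 2942 genes the covered share was at least 50% in both replicates, and in 427 it was at least 80%. The marked share was 18.3% among genes of 1 to 5 kb, 33.0% at 5 to 20 kb, 35.2% at 20 to 100 kb and 8.11% at 100 kb or longer. The threshold for a marked gene was set before the data were examined, and the count moved to 7307 at 10% and to 2942 at 50%.

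Long genes were found at both extremes. Cit, which encodes citron kinase of cytokinesis, carried 139 kb of replicated peaks and was covered over 80.4% ± 0.148 of its 164 kb. Ubr4, a ubiquitin ligase, reached 89.2% ± 0.112 over 137 kb, Hectd4 reached 78.6% ± 0.0524 and Taok3 reached 66.2% ± 1.15. Atp8a1, Wdfy3 and Asap1 were covered over 50.1% ± 0.683, 42.6% ± 1.17 and 38.1% ± 0.454. Gm20388 and Fgfr2 had the greatest covered lengths, 794 kb and 202 kb, but the annotation draws them over 4435 kb and 2961 kb and places 50.4% and 53.2% of them inside other protein-coding genes. The 10 longest genes with no covered base in any list were Lsamp, Lrp1b, Macrod2, Dlg2, Pcdh15, Rbfox1, Grid2, Il1rapl1, Lrrc4c and Il1rapl2, several of which encode synaptic or neuronal adhesion proteins. Lsamp was the longest, at 2197 kb on chromosome 16.

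Erythroid genes were marked nearly throughout. Of 29 listed erythroid genes, 25 were marked, including Epb42 and Slc4a1, components of the red cell membrane, at 89.5% ± 0.221 and 87.4% ± 0.0936, and Ermap at 88.5% ± 0.311. The transferrin receptor gene Tfrc stood at 84.0% ± 0.272 and Zfpm1, a cofactor of the erythroid regulator Gata1, at 81.0% ± 0.518. All of Zfpm1 lies inside the long gene model Gm20388. Gata1 itself, on X, was lower at 24.8% ± 1.54. The other 4 members were the globin genes Hbb-bt, Hbb-bs, Hba-a1 and Hba-a2, which had no covered base in either replicate. All 9 genes of haem biosynthesis were marked, from Fech at 79.0% ± 1.13, Ppox at 78.7% ± 1.59 and Urod at 77.5% ± 2.38, through Hmbs at 69.7% ± 0.0538, Alas2 at 66.8% ± 3.27, Uros at 59.3% ± 2.09, Alad at 58.2% ± 1.73 and Alas1 at 53.0% ± 2.37, down to Cpox at 21.3% ± 0.381. Of these, Alas2 lies wholly inside another protein-coding gene model. Random lists of the same gene lengths held 4 to 13 marked genes for the erythroid list and 1 to 6 for haem biosynthesis in their central 95%.

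Few hepatic genes were marked, although many hepatoblast genes were partly covered. Of 27 hepatoblast genes only Ambp, at 38.4% ± 9.93, was marked, 18 were partly covered and 8 had under 5% in both replicates. The count of marked hepatoblast genes was 2 in replicate 2 alone, 3 on the replicated list and 5 on the joint list. Their median covered share, 5.34%, stood at percentile 83.9 of random length-matched lists, above the middle, while the count of marked genes stood low. Plg, which encodes plasminogen, had 20.2% ± 2.88 and Apob, the main protein of very-low-density lipoprotein, 16.3% ± 2.65. Alb and Afp, encoding the main fetal plasma proteins, had 0.796% ± 1.13 and 1.59% ± 2.2, all of it from replicate 1, and Apoa1, Apoa2 and Foxa1 had no covered base. None of 22 genes of adult hepatocyte metabolism was marked, and 1 was in replicate 2 alone and on the replicated and joint lists. The highest of these were the urea cycle genes Ass1 and Arg1 at 22.9% ± 6.25 and 12.4% ± 3.71 and Aldob at 6.62% ± 0.386, while Cps1 and Otc had no covered base. Of 21 coagulation and complement genes, Cfb (38.7% ± 4.93) and C3 (25.9% ± 1.12) were marked, and 99.4% of Cfb lies inside another protein-coding gene model. That count was 4 in replicate 2 alone and on the replicated and joint lists, and 1 with −log10 p of at least 5. None of 12 cholangiocyte genes was marked, with Aqp1 highest at 9.64% ± 6.47, and 1 was on the joint list. Central ranges of random length-matched lists were 4 to 13 marked genes for the hepatoblast list, 3 to 11 for adult hepatocyte metabolism, 3 to 12 for coagulation and complement and 1 to 6 for cholangiocytes.

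**Figure D1:**
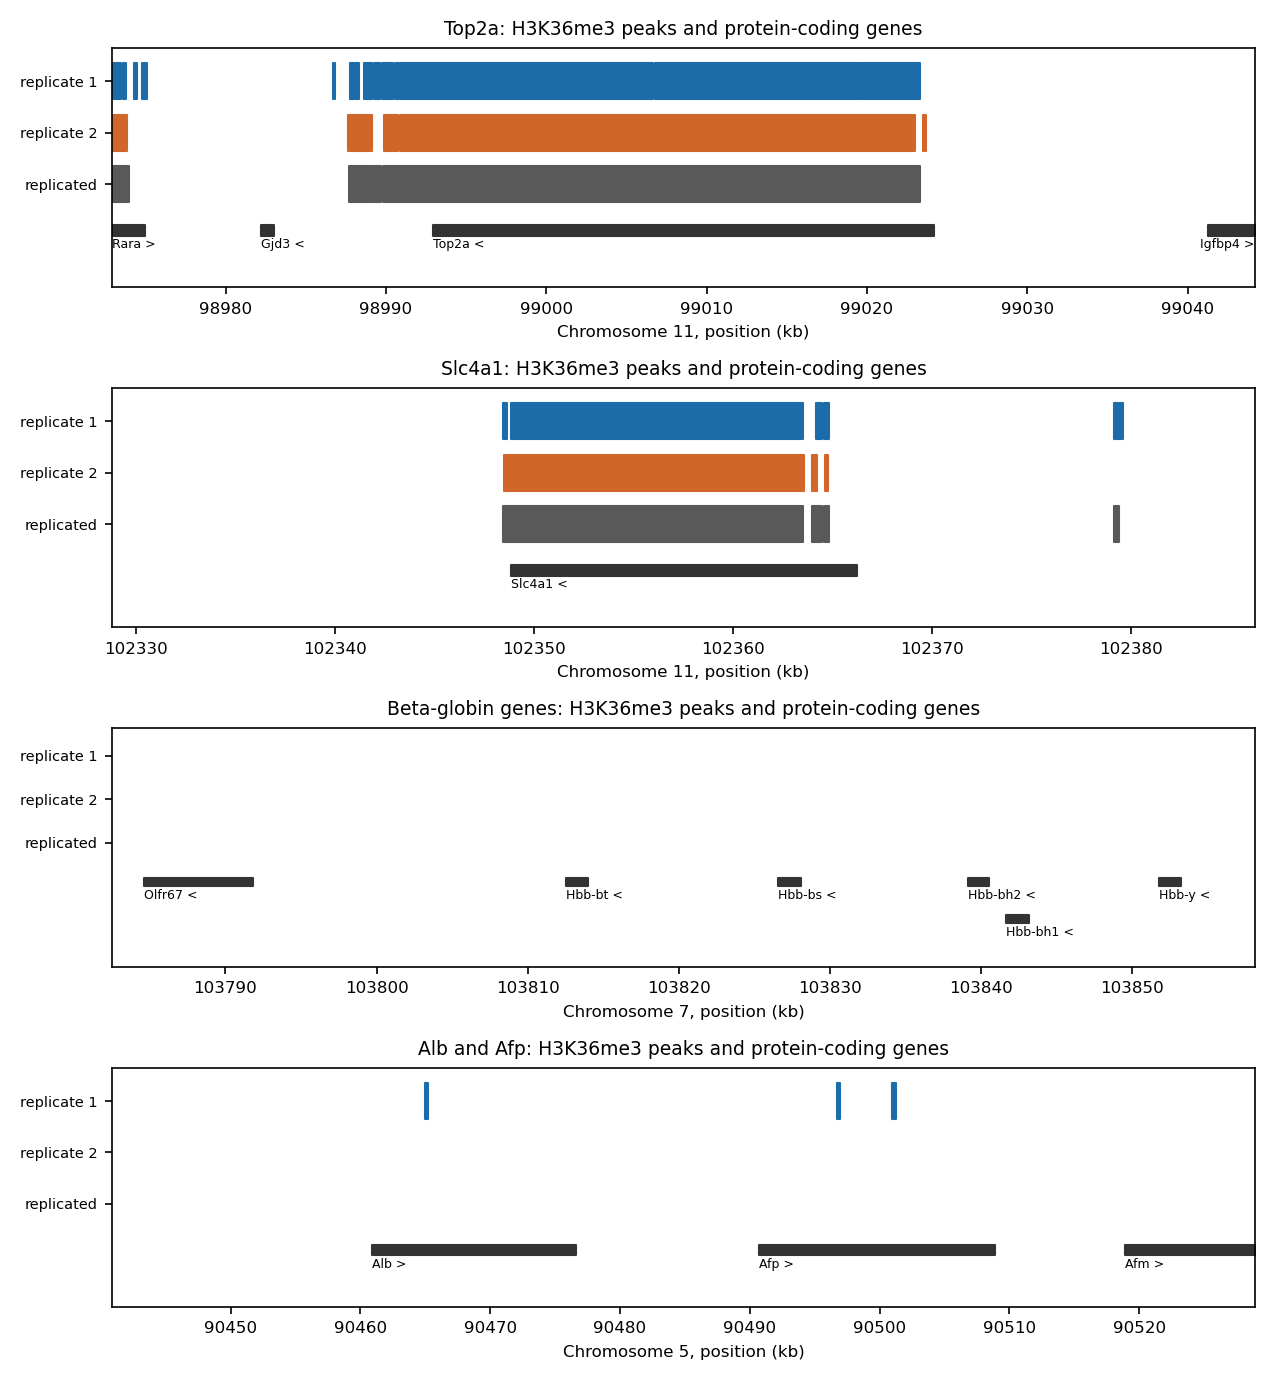
H3K36me3 peaks of replicate 1, replicate 2 and the replicated list (bars, by position in kb on mm10) over protein-coding genes (dark bars with strand arrows) at Top2a, Slc4a1, the beta-globin genes, and Alb with Afp. Peaks fill Top2a (96.5%) and most of Slc4a1 (87.4%), none lies over the beta-globin genes, and Alb and Afp hold short peaks in replicate 1 alone.

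Markers of the other cell types of the organ were mostly not marked. Among 16 genes of haematopoietic stem and progenitor cells, Lyl1 (65.7% ± 0.152, wholly inside another gene model) and Myb (29.6% ± 0.0255) were marked, while Kit had 11.2% ± 0.470 and Cd34 and Hoxa9 had no covered base. The count of marked stem and progenitor genes was 4 on the replicated list and 5 on the joint list. Of 15 megakaryocyte genes only Nbeal2 was marked, at 25.7% ± 1.52; Gp9 had 40.9% in replicate 1 and 13.2% in replicate 2. Of 19 myeloid and macrophage genes only Cd68 was marked, at 98.6% ± 2.04, and the replicated peak over it, on chromosome 11 from 69663530 to 69667015, reached into Eif4a1, a marked neighbour at 70.8% ± 3.09. Of 15 endothelial genes only Stab1, a scavenger receptor of sinusoidal endothelium, was marked, at 26.4% ± 0.387, and of 17 lymphoid and 14 mesenchymal and stellate genes none was. With −log10 p of at least 5, neither Nbeal2 nor Stab1 was marked, and on the joint list 2 megakaryocyte and 3 endothelial genes were. Pdgfrb had 5.43% ± 0.221 and Cd79b 2.56% ± 3.62. Of 20 neuronal genes, 17 muscle genes and 26 developmental transcription factors of other tissues none was marked, and the highest members were Syt1 at 0.117% ± 0.0347, Ttn at 1.10% ± 0.266 and Pax6 at 0.316% ± 0.447. Central ranges of random length-matched lists were 1 to 7 marked genes for stem and progenitor and for megakaryocyte genes and 0 to 4 for neuronal genes. The counts of these lists lay in neither tail of 2.5%. The ranges were 2 to 9 for myeloid genes, 1 to 8 for lymphoid, endothelial and mesenchymal genes, 2 to 8 for muscle genes and 3 to 11 for developmental factors.

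Genes of cell division and of general cell machinery were marked in nearly every case, and those of H3K36 methylation less often. Of 26 cell cycle genes 25 were marked, the exception being Pola1 on X at 7.03% ± 0.883, and the next lowest was Bub1 at 50.7% ± 1.70. All 23 genes of general cell machinery were marked, led by Kpnb1, the elongation factor gene Eef2 (89.1% ± 4.55) and the chaperonin gene Cct2 (88.3% ± 0.177), with Gapdh at 43.6% ± 7.44 and Hprt on X at 26.5% ± 5.91 lowest. Of 83 ribosomal protein genes 73 were marked, with Rps15a at 87.6% ± 1.44 and Rpsa at 85.4% ± 3.02, and Rpl3l and Rpl39l had no covered base. Of 16 genes that write, read or remove H3K36 methylation 10 were marked, with the demethylase gene Kdm4a (84.3% ± 1.28), Psip1 (68.9% ± 0.195) and Nsd2 (62.0% ± 1.22) highest, the methyltransferase gene Setd2 at 53.9% ± 1.16, and Kdm2b and Kdm4c lowest at 5.78% ± 0.996 and 5.31% ± 0.0701.

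Large gene families stood at opposite ends. Of 391 C2H2 zinc finger genes named Zfp, 165 were marked against a central range of 114 to 149 in random lists, from Zfp869 (97.9% ± 0.0322) and Zfp335 (89.3% ± 0.470) to Zfp804b and Zfp536 with no covered base. From 50% covered, 55 Zfp genes were left, close to the 13.9% of all protein-coding genes at that threshold. Of 1093 olfactory receptor genes 1 was marked against 288 to 346, and none of 327 vomeronasal receptor genes against 79 to 109. The marked receptor gene was Olfr419 (64.4% ± 13.5), and its replicated peak, on chromosome 1 from 174248587 to 174251030, began 0.136 kb past the end of the erythroid spectrin gene Spta1. Of 49 keratin genes only Krt18, a keratin of simple epithelia, was marked, at 26% ± 5.49, and not with −log10 p of at least 5. Of 67 replication-dependent histone genes none was marked, the highest being Hist3h2a at 10.4% ± 2.08, wholly inside another gene model. Among 22 imprinted genes 6 were marked, with Impact at 51.3% ± 0.0133, Nnat (wholly inside another protein-coding gene, whose coverage it shares) at 46.4% ± 7.55 and Igf2r at 37.1% ± 4.65 highest, a count within the 2 to 10 of random lists. The imprinted count fell to 3 with −log10 p of at least 5 and when marked from 30%.

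By the median covered share of their members, 7 of the 25 lists lay in the top 2.5% of 10000 random lists of matched gene length. These were the erythroid, haem biosynthesis, cell cycle, general machinery, H3K36 machinery, ribosomal and Zfp lists, with median covered shares of 66.8%, 66.8%, 84.7%, 68.8%, 46.1%, 64.7% and 16.2%. No list lay in the bottom 2.5% by its median, which is near 0 in random lists too. The percentiles were 83.9 for the hepatoblast list, 82.4 for stem and progenitor cells, 89.7 for imprinted genes, 44.9 for coagulation and complement and 13.6 for adult hepatocyte metabolism. They were 17.1 for cholangiocytes, 26.8 for megakaryocytes, 29.6 for myeloid cells, 26.5 for lymphoid cells, 18.4 for endothelium, 25.2 for mesenchyme, 8.67 for neuronal, 9.09 for muscle and 30.9 for developmental factors. The percentiles of the olfactory, vomeronasal, histone and keratin families were 50, 47.9, 50 and 44.4. Counting marked members in place of the median, a statistic chosen after the data were examined, put the same number of lists in the top 2.5% and 14 in the bottom 2.5%, the hepatoblast list among them. The percentiles describe these libraries and carry no p-value.

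**Figure D2:**
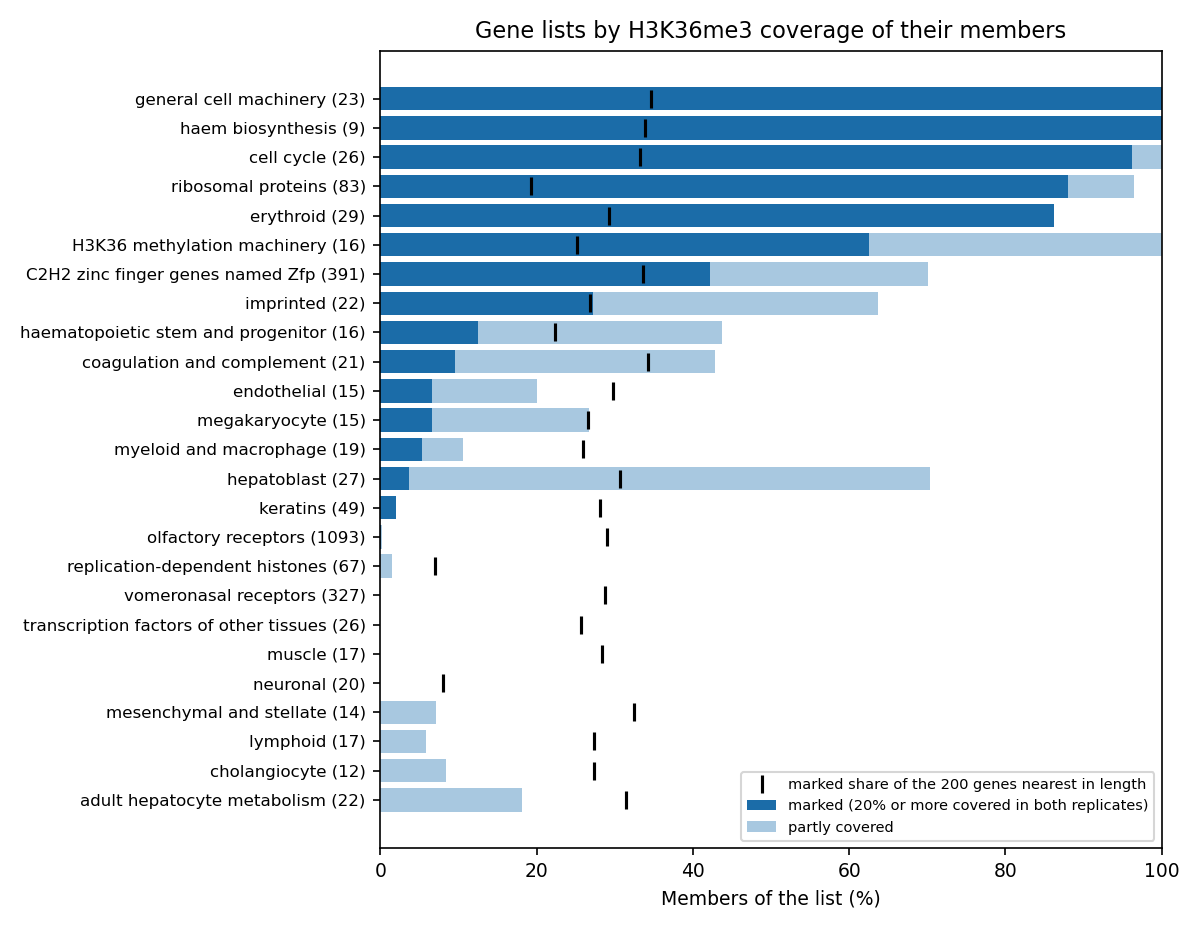
Share of each gene list's members (x axis, %) that were marked (dark bars) or partly covered (light bars), with the number of members in brackets and the marked share among genes nearest in length (black ticks). Erythroid, haem, cell cycle, general machinery and ribosomal lists lie far right of their ticks, and the hepatoblast list has 1 of 27 marked and 18 partly covered.

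The mark rose along the gene body towards the 3' end. In 5420 marked genes of at least 5 kb, 65.8% ± 0.282 of the 3' side of the midpoint was covered and 38.2% ± 0.573 of the 5' side (SD, n = 2). The difference was 27.5 ± 0.291 points and was positive in 88.4% of these genes. Coverage was 8.42% ± 0.281 in bin 1 of 10 along the gene body, peaked at 69.7% ± 0.109 in bin 9 and was 63.8% ± 0.161 in bin 10. It continued past the annotated end, at 48.4% ± 0.495 in the kilobase downstream, and was 1.68% ± 0.0547 in the kilobase upstream. In 721 marked genes with no other annotated gene within 5 kb, the kilobase downstream was covered over 44.2% ± 0.468, the window 5 kb downstream over 5.48% ± 0.503 and the kilobase upstream over 0.0681% ± 0.0577.

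Individual genes departed widely from this average. Slc29a1, a nucleoside transporter gene, had a difference of 97.9 points, Reep6 93.3, the splicing-related gene Srrm2 92.1 and Capns1 91.5, and Gnb2, which shares 95% of its body with another gene model, had 98.2. The lowest values, from -95.3 to -76.5 points, belonged to Gm42421, Gm20538, AC129217.1, Gm20708 and Gm28374, gene models that share from 47.3% to 100% of their length with other protein-coding genes. Vps13d, with no overlapping protein-coding gene, had -42.5 points over 222 kb. Among noncoding genes of at least 5 kb outside protein-coding genes, 5430416N02Rik (78.5% ± 3.78), Snhg17 (75.8% ± 0.314), Malat1 (74.9% ± 1.84), AU020206 (69.2% ± 1.12) and Gm20342 (67.5% ± 6.49) had the highest covered shares.

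**Figure D3:**
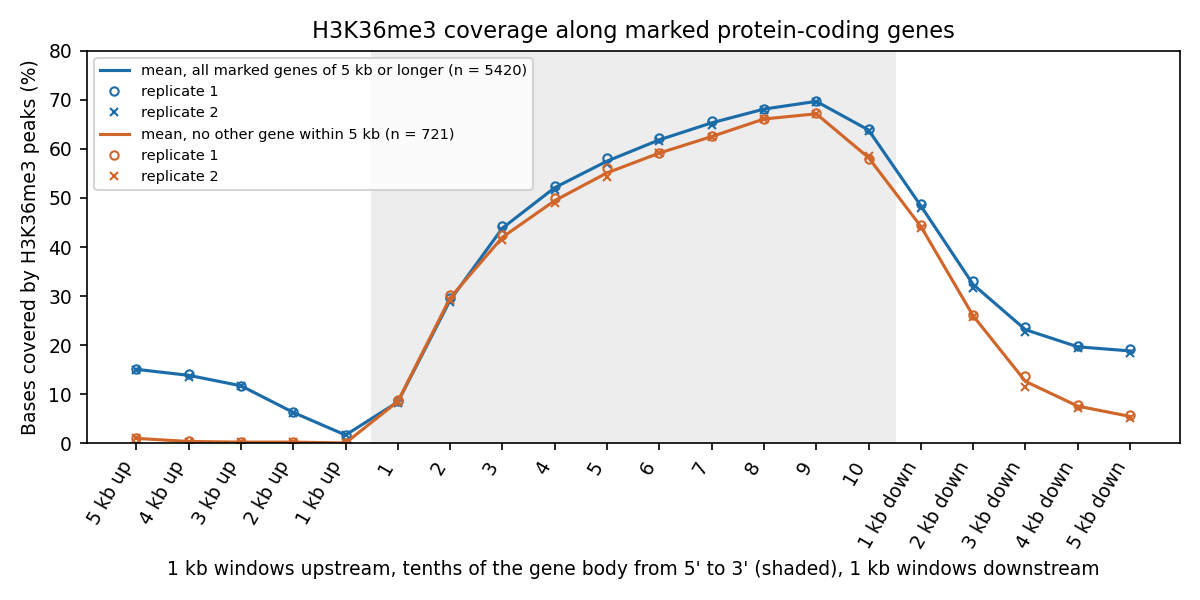
Percent of bases covered by H3K36me3 peaks (y axis) in windows of 1 kb around and 10 equal bins of the gene body (shaded) along marked genes of at least 5 kb, for all 5420 genes and for the 721 with no other gene within 5 kb (lines, means; circles and crosses, replicates 1 and 2). Coverage climbs from 8.42% in bin 1 to 69.7% in bin 9 and falls off downstream of the gene.

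Internal exons were covered more than introns of the same gene. Over 5719 marked genes of at least 3 exons, 74.5% ± 0.25 of internal exon bases and 50.6% ± 0.502 of intron bases lay under peaks (SD, n = 2). The difference was 23.9 ± 0.252 points, with exons higher in 84.1% ± 0.445 of genes. Within the 3' side of the gene the difference was 16.8 ± 0.163 points. Against the adjacent 200 bp of intron on each side, a comparison chosen after the data were examined, it was 7.72 ± 0.0148 points in 4788 genes, 76.2% against 68.4%. Simulated lists that covered the 3' part of 2000 genes without regard to exons gave 7.54 points against whole introns, under a steeper 3' rise than in the data. Those genes were not chosen as marked and were covered evenly over the 3' part, without the gradual rise of the data. The value therefore sets no bound on what position along the gene adds here. The adjacent 200 bp were not simulated.

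H3K36me3 peaks were concentrated in genes. They covered 9.29% ± 0.166 of the bases of protein-coding genes and 0.0246% ± 0.00592 of intergenic sequence at least 5 kb from any gene, a 388 ± 86.8-fold difference (SD, n = 2). Protein-coding genes held 94.9% ± 0.167 of all covered bases. Against every base outside genes, which includes the stretches just downstream of marked genes, the fold was 30.6 ± 1.15, and with −log10 p of at least 5 the main comparison gave 653 ± 44.7. The highest peak signal of the replicated list, 26.6 on the authors' scale, lay over Zfpm1 on chromosome 8 from 122332664 to 122340863, followed by peaks over Trim56 (19.4), Srrm2 with Elob (18.6), Ccnf (18.0) and Cit (17.7).

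Few genes on X were marked. Of 877 protein-coding genes on X, 78 were marked, 8.89% with an exact 95% binomial interval of 7.09% to 11%, against 5967 of 20181 on the autosomes, 29.6% with an interval of 28.9% to 30.2%. Taken per replicate, the X share minus the autosomal share was -20.9 ± 1.11 points (SD, n = 2). The lowest autosome, chromosome 14, had 20.5% of its genes marked and the highest, chromosome 8, had 37.5%. None of 163 genes on Y was marked. Marked genes on X had a median covered share of 38% and marked autosomal genes 51.2%. At a threshold of 50% covered, which 13.9% of all protein-coding genes reached in both replicates, the difference was -13.1 points. With fewer genes marked in all, these points are not on the scale of the main threshold. The intervals cover counting error over genes, which are not independent replicates.

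**Figure D4:**
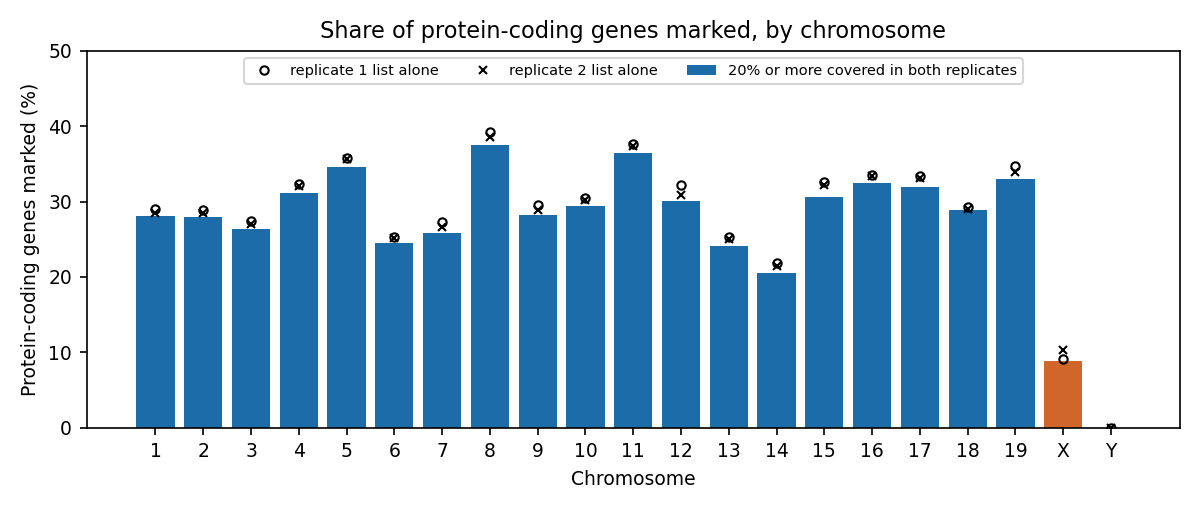
Share of protein-coding genes with at least 20% of the body covered (y axis, %) by chromosome, in both replicates (bars) and in each replicate list alone (circles and crosses), with X and Y in orange. X stands at 8.89%, below every autosome (20.5% to 37.5%), and Y at 0.

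The replicates shared most of their covered sequence. The base overlap of their lists, the Jaccard index, was 63.0%, or 78.7 Mb shared, against 1.96% to 2.64% in 100 circular shifts of replicate 2. At least 50% of the length was covered by the other replicate in 64.1% of replicate 1 peaks and in 67.7% of replicate 2 peaks, against means of 4.31% and 4.40% under the shifts. The covered shares of 11556 genes with a covered base had a Pearson r of 0.985 across genes, which are not independent replicates. In marked genes the replicates differed by a median of 2.44 points, with a 95th percentile of 10.2, and 20 marked genes differed by over 20 points.

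The 10 genes of at least 5 kb with the largest differences between replicates were all under 10 kb long. Arl2, a small GTPase gene, was covered over 49.3% in replicate 1 and 6.10% in replicate 2, Gtf2h5 over 48.6% and 24.1%, and Slc39a5 over 25.6% and 3.51%. The order was the opposite in Lrrc45 (18.3% and 43.9%) and Pias3 (18.8% and 40.4%), and in Abt1 and Wdr13. Mrpl44, Spata24 and Ung, covered more in replicate 1, completed the group.

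Few replicated peaks lay away from genes. Of 110076 replicated peaks on the chromosomes, 4000 (3.63%) touched no annotated gene and 327 lay at least 5 kb from any annotated gene, 0.297% with an exact 95% interval of 0.266% to 0.331%, and 86 of these lay within a RefSeq gene model. The highest signal, 7.63, belonged to a peak on chromosome 3 from 27089277 to 27089998, 7.22 kb downstream of Ect2, a regulator of cytokinesis, with no RefSeq gene at the site. The next lay on chromosome 6 from 38617709 to 38619248, 6.44 kb downstream of Klrg2 and inside the RefSeq model of that gene. Peaks on chromosome 5 from 104582944 to 104583719 and from 104583897 to 104584368 lay in the RefSeq model of Zfp33b, and one on chromosome 4 from 12104821 to 12107039 in that of Rbm12b2. The remaining sites of the 10 highest were on chromosome Y from 90740900 to 90743163, chromosome 17 from 17204768 to 17206180, chromosome 12 from 108778925 to 108779455 and chromosome 5 from 146308254 to 146309632, all in RefSeq gene models named Gm, and on chromosome 11 from 121943414 to 121943850, in none.

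The replicated list was a subset of the list called on both replicates together. All 110088 of its peaks matched a record of that list by position and name, and they made up 68.3% of it. Of 77301 joint peaks with at least 50% of their length covered in each replicate, 77300 were kept, but such peaks were 70.2% of the replicated list. Requiring 50% of either the joint or the replicate peak, a rule tried after the data were examined, accounted for 91988 replicated peaks and left 18100. A total of 17521 replicated peaks, 15.9%, had no covered base in at least 1 of the replicates, and 981 of them had none in either. These 17521 had a median signal of 2.64 and a median length of 334 bp, against 3.49 and 685 bp for the rest, and held 5.77% of the list's bases.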

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

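Of the tests in this part, those of gene length, of the share of erythroid cells and of hepatoblasts, and both tests on X were chosen after the values they rest on had been seen. Their limits were rewritten once those values were known, and the test of weaker detection on X replaced an earlier one that had decided nothing. The counts of 32-mers were planned beforehand and kept. The design holds a single group, so no biological explanation could be tested against another group.

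The replicated list held 12 peaks on unplaced or unlocalized scaffolds, which no comparison with genes uses. The comparison of the replicated list with the joint list and the replicate lists counts them. Their signal ranged from 1.37 to 14.

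The globin genes Hbb-bt, Hbb-bs, Hba-a1 and Hba-a2 had no covered base although the other erythroid genes were marked. A small share of erythroid cells is argued against by the 25 other erythroid genes, 100% of which were marked. Shortness alone did not keep all genes unmarked, since 13 of 18 ribosomal protein genes within 1.5 times of a globin gene's length were marked. Their share was 72.2%, with an exact 95% interval of 46.5% to 90.3%. The ribosomal list was, however, itself in the top 2.5% by its median. Of all genes of 1 to 5 kb 18.3% were marked. Random lists matched in length to the 67 replication-dependent histone genes (median 0.539 kb) held 1 to 9 marked genes. The histone list itself held 0, in the bottom 2.5%, so its count does not reflect length alone. With few short genes marked, a part played by length stays open. What also stays open is that reads from these genes may not map to one place. Only 3.46% of the 32-mers of Hba-a1, the lowest, and 4.11% of those of Hba-a2 occur once in GRCm38. For Hbb-bt and Hbb-bs the shares were 25.6% and 29.96%. In ribosomal protein genes the median was 84.1%, so a lack of peaks over the globin gene bodies may say little about the mark there. The window of 75.6 kb around Hbb-bt and Hbb-bs also held no peak in either replicate or in the replicated list. Peaks covered only 0.304% ± 0.0169 of all bases outside genes, so sequence away from marked genes is mostly empty without any loss of reads. The 32-mers of the sequence beside the globin genes were not counted either, so its lack of peaks does not decide the question.

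The hepatoblast genes Alb, Afp, Apoa1, Apoa2, Apoh, Fgb, Foxa1 and Prox1 had under 5% of their body covered in both replicates. Reads that map to several places are argued against, since a median of 98.7% of the 32-mers of these genes occur once. Gene length was not settled by the test made. Of 57 ribosomal protein genes within 1.5 times of the length of any of the 8, 50 (87.7%) were marked. That is close to the 73 of 83 (88.0%) in the whole ribosomal list, so it says little about length. Matches were pooled over lengths of 1.33 to 71.0 kb, not made for each gene. Among all protein-coding genes, 33.0% of those of 5 to 20 kb and 35.2% of those of 20 to 100 kb were marked. Of those of 1 to 5 kb, the class of Apoa1 and Apoa2, 18.3% were marked. Such lengths thus did not prevent marking, though the shortest class was marked less often than these 2 classes. A small share of hepatoblasts among the cells cannot be told apart from a true lack of the mark, since the share of each cell type was not measured. Among lists of 5 other cell types (endothelial, megakaryocyte, mesenchymal, myeloid and lymphoid) the highest marked share was 6.67%, close to the 3.70% of the hepatoblast list. Partial coverage differed: it held for 18 of 27 hepatoblast genes, against 3 of 15 megakaryocyte, 2 of 15 endothelial and 1 of 14 mesenchymal genes. In the myeloid and lymphoid lists it held for 1 of 19 and 1 of 17. To be partly covered a gene needs 5% in only 1 replicate, and Foxa3, Vtn, Cebpa and Itih3 had no covered base in the other. The counts were not matched on length. Median gene length was 10.5 kb in the hepatoblast list and 10.8 and 10.9 kb in the myeloid and lymphoid lists. In the other lists compared it was 15.1 to 42.9 kb. These counts are over whole lists, not the 8 genes named here. Both readings remain open for these 8 genes.

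Genes on X were marked less often than autosomal genes. If X merely held fewer broadly used genes, X members of the 6 broadly marked lists should be marked as often as the others; 5 of 8 were (62.5%, exact 95% interval 24.5% to 91.5%) against 157 of 175 autosomal members (89.7%; two-sided Fisher exact p = 0.0502), which leaves this open. The median covered share of the same 8 genes was 25.7%, at percentile 0.038 of 100000 random sets of autosomal members of the same lists, whose medians centred on 69.3%. The 6 lists were chosen as broadly marked in these same data, and the Zfp list, also in the top tail, was not among them. A low median of 8 genes cannot tell weaker detection on X as a whole from less of the mark at these genes. Weaker detection stays a candidate, for which the pool of both sexes with 1 active X per cell would be a reason that was not tested. The 8 members were Alas2, Rps4x, Rpl39, Hprt, Gata1, Rpl10, Rpl36a and Pola1, and 7 of them reached 20% in replicate 2 alone. Rpl10 had 38.3% there against 9.68% in replicate 1, and Rpl36a 35% against 0. In replicate 1 alone Rpl10, Rpl36a and Pola1 stayed under 20%. The 7 of 8 lie within 10 points of the autosomal share, but that share required 20% in both replicates. Gene content therefore stays open.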

How the results depend on the processing

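The rule of 50% of either peak, the number of marked members in place of the median, introns without repeats and the adjacent 200 bp of intron were settings chosen after the data were examined, and the others were fixed beforehand. No difference or fold changed sign under any setting and no list went from the top to the bottom 2.5%, but some percentiles crossed the middle, and the cause of the moves below was not tested except where a setting's construction shows it. With −log10 p of at least 5, base overlap was 64.9%, peak sharing 67.6% (replicate 1) and 69.1% (replicate 2), enrichment 653-fold, 3' minus 5' 29.2 points, exon minus intron 24.3 points, X minus autosomes -19.3 points and peaks outside genes 0.265%. With −log10 q of at least 2 these were 63.9%, 64.9%, 69.3%, 486-fold and 28.1 points for the 3' minus 5' difference. Peak sharing by 1 bp was 73.5% and 76.8%, and by 80% of peak length 45.9% and 49.1%. The share of replicated peaks covered in both replicates was 84.1% by 1 bp, 33.9% by 80% and 83.6% by 50% of either peak. On the replicated list, enrichment was 544-fold, 3' minus 5' 28.8 points, exon minus intron 24.2 points and X minus autosomes -22.1 points, and on the joint list the last was -23.3. Against every base outside genes, enrichment was 30.6-fold. The 3' minus 5' difference was 33.5 points at 5 to 20 kb, 22.3 at 20 to 100 kb, 23.3 over 100 kb and 25.7 with no other gene within 5 kb. Exon minus intron was 16.8 points in the 3' part, 21.7 against introns without repeats and 7.72 against the adjacent 200 bp. Marked from 50% covered, 2942 genes were left. X minus autosomes was -23.2 points when marked from 10%, -17.9 from 30%, -13.1 from 50%, and -23.0 without olfactory, vomeronasal and keratin families. Peaks outside genes were 3.63% at 1 bp and 0.0382% at 20 kb from any gene.

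By the number of marked members, percentiles were 0.045 for hepatoblast, 0 for adult hepatocyte metabolism, 0.475 for coagulation and complement, 0.985 for cholangiocyte, 1.17 for myeloid, 0.175 for lymphoid, 1.74 for endothelial, 0.185 for mesenchymal, 0.105 for muscle, 0.035 for developmental factors, 0 for olfactory, 0 for vomeronasal, 0.34 for histones and 0 for keratins, all now in the bottom 2.5%. By the median the hepatoblast list had stood at 83.9, so its place depends on the statistic, and the stem and progenitor list went from 82.4 to 17.3. Unmatched random lists put the olfactory family at 0.015 and took coagulation and complement from 44.9 to 78.6. The other 185 percentiles under alternatives kept their side of the limits, as did 182 counts of marked members within 1.5 times, while 43 counts moved further. Leaving out each replicate in turn, 3' minus 5' ranged from 27.1 to 27.6 points, exon minus intron from 23.8 to 24.1, enrichment from 327 to 450, X minus autosomes from -21.7 to -20.1 and marked genes from 6226 to 6302, and 7 lists stayed above each time. Depth is unknown, so an uncovered gene is one without a called peak and its mark may lie below detection: Alb went from 1.59% covered in replicate 1 to 0 in replicate 2.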

Other observations

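These observations were chosen after the values had been seen. Replicated peaks close to the end of marked genes also lay over genes of other cell types. Cd68, the only marked gene of the myeloid list, and Olfr419, the only marked olfactory receptor, each lay under a peak that reached a marked gene or lay close to its end, Eif4a1 for Cd68 and Spta1 for Olfr419. Spta1, a red cell membrane skeleton gene of the erythroid list, was covered over 73.2% ± 1.56 (SD, n = 2). In marked genes with no neighbour within 5 kb, 44.2% ± 0.468 of the kilobase past the annotated end was covered, so a covered share of a short gene close to the end of a marked gene does not identify that gene as the source.

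Among imprinted genes, Cdkn1c (25.2% ± 0.521), Gnas (25.6% ± 2.74) and Peg3 (22.6% ± 0.293) were also marked, whereas Igf2, nearly all of which lies inside another gene model, had 3.4% ± 0.727 and H19 no covered base. Dlk1 and Meg3 had 9.11% ± 7.67 and 8.39% ± 4.29, with replicate 2 higher in both.

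Genes of H3K36 methylation and of DNA methylation differed among themselves. Nsd1, Nsd3 and Ash1l encode enzymes that add lower degrees of H3K36 methylation, not H3K36me3 itself. The genes Nsd1 (60.9% ± 1.33), Nsd3 (49.5% ± 0.747) and Ash1l (49.2% ± 0.294) were marked, and the DNA methyltransferase genes Dnmt3a (16.6% ± 1.11) and Dnmt3b (5.92% ± 3.19) were not.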
